A study of Homo sapiens with 4 samples.

How the data were processed

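Gene expression was measured by RNA sequencing in 4 libraries of A549 cells, 2 infected with a control hairpin lentivirus (shControl) and 2 with a hairpin lentivirus against RALY (shRALY). Group and replicate number were taken from the sample titles. Per the labels' protocols, cells grew in medium with 10% FBS, total RNA was extracted with Trizol, and 1 µg of RNA per sample was selected on poly-T beads, fragmented and made into Illumina TruSeq libraries with a preferred insert of 370 to 420 bp. Poly-T selection samples polyadenylated transcripts, so transcripts without a poly(A) tail, such as most replication-dependent histone mRNA, are poorly represented.

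The deposited files hold raw counts per Ensembl gene, 1 file per library, neither normalised nor pooled. Per the submitters' processing notes, the tools used were HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the hg38 build; the notes give them no role or order. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Each file held 58735 genes, and all 58735 identifiers matched GENCODE release 29 on GRCh38, which supplied symbols, biotypes and coordinates. In 1 file, 1 line was separated by a space instead of a tab and was read the same way. Total counts ranged from 16745818 to 18632787 per library, so 3 counts, the floor used for a gene with no counts, correspond to 0.161 to 0.179 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

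Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and the quasi-likelihood F-test with robust estimation compared shRALY with shControl, with 2 residual degrees of freedom and no covariate. The filter kept 15912 genes, which held 99.83% of counts, and left out 42823. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. A standard error is the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled library sizes. Where a gene had no control counts, its fold change is a bound against 3 counts over the shControl group; with 1 to 3 control counts, the ratio of counts is given with an exact 95% binomial interval.

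Before the data were examined, 32 gene lists, the tests, most of the alternatives and the rule for naming genes were set. The rule took RALY first, then the 12 highest and 12 lowest log2 fold changes among protein-coding genes past the test, with a mean of at least 5 CPM in a group and with both shRALY libraries on the same side of both shControl libraries. It added up to 4 members of each list with the smallest adjusted p, or where fewer than 2 passed the most abundant members to make 2, and HNRNPC, RALYL and E2F1 in any case. Lists with at least 5 tested members were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 30 lists tested; camera with an estimated correlation and fry were run beside it. Camera with an estimated correlation rests on the 2 residual degrees of freedom, which limits how small its p-values can become here. Gene E2F1 stands in 2 lists, as do ME1, SESN2 and SLC7A11.

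Both count tests were checked on simulated counts drawn from the shControl means and the library sizes of this comparison, with 15372 genes tested. Changes of log2 0.5, 1 and 2 were given to 67, 67 and 66 genes. At log2 changes of 0.5, 1 and 2, edgeR recovered 41.8%, 70.1% and 92.4% of changed genes, and 8.7% of its calls were unchanged genes. DESeq2 1.42.0 recovered 19.4%, 64.2% and 87.9%, with 5.8% of its calls unchanged. Small changes were thus found incompletely in this simulation, with 2 libraries per group. Far fewer genes changed there than the 41% of tested genes called in the real data. The recovered and false shares can differ where so many genes change.

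Shared sequence was measured for 254 named or grouped genes, as the share of 50-base words of the longest transcript that also occur in the longest transcript of another gene, and as exonic bases overlapped by other genes on either strand. Genes above 20% on either measure are named as uncertain where they appear, since the counting of such reads is not stated and the counts cannot be assigned to a strand. GC content and transcript length were taken from the longest GENCODE transcript and were available for 99.9% of tested genes.

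Alternatives were DESeq2, RLE size factors, library size alone, no filter on low counts, a filter of 10 CPM in 2 libraries, no robust estimation, the replicate number as a block, each library left out in turn, and protein-coding genes alone. A correction for GC content and transcript length and a test against a 1.2-fold change (glmTreat) were chosen after seeing the data. With groups of 2, counts of other splits of the samples were not made. Leaving out a library leaves its group with 1, so the spread is then that of the other group's pair. Some members of the lists are not reported here by name.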

Results

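The comparison asked how depletion of RALY, an RNA-binding protein of the hnRNP family, altered the transcriptome of A549 cells, a human lung adenocarcinoma line that the labels describe as alveolar basal epithelial cells. Cells were infected with a lentivirus carrying either a control hairpin (shControl) or a hairpin against RALY (shRALY), and polyadenylated RNA was sequenced at a time labelled day 2. There were 2 libraries in each of the 2 groups. The deposited gene counts summed to 17587717 and 16745818 in shControl replicates 1 and 2, and to 18632787 and 16823605 in shRALY replicates 1 and 2. Across the 14250 genes with a mean of at least 1 CPM, log2 CPM correlated at Pearson's r = 0.992 between the shControl libraries and 0.995 between the shRALY libraries, against 0.933 to 0.938 between groups; these are correlations across genes, which are not independent replicates. Libraries of a group differed by more than counting noise, with a chi-square per gene of 11.8 for shControl and 4.92 for shRALY. The labels do not state that replicates were separate cultures, so the p-values measure the spread between these libraries, which could be technical. Levels are given as normalised read counts in CPM, mean ± SD with n = 2 libraries per group.

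RALY mRNA was 3.12-fold lower in the shRALY libraries, at 32.1% of the control level. RALY (ENSG00000125970) lies on the plus strand of chromosome 20, at 33993646 to 34108308 in GRCh38, and is annotated as protein coding. Its raw counts were 2208 and 2272 in shControl and 751 and 679 in shRALY, or 128 ± 7.15 CPM against 41.2 ± 0.47 CPM. The log2 fold change was -1.64 (SE 0.11; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.85e-11). HNRNPC, the closest well-expressed relative of RALY, stood at 528 ± 35.9 CPM in shControl and 411 ± 11.5 CPM in shRALY, a log2 fold change of -0.36 (SE 0.10; edgeR adjusted p = 0.0058). The HNRNPC call was lost without shRALY replicate 1 (log2 -0.39, edgeR adjusted p = 0.122) and without shRALY replicate 2 (log2 -0.32, edgeR adjusted p = 0.204). RALYL, a paralog, had 0 counts in every library, which allows at most 0.161 to 0.179 CPM.

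**Figure D1:**
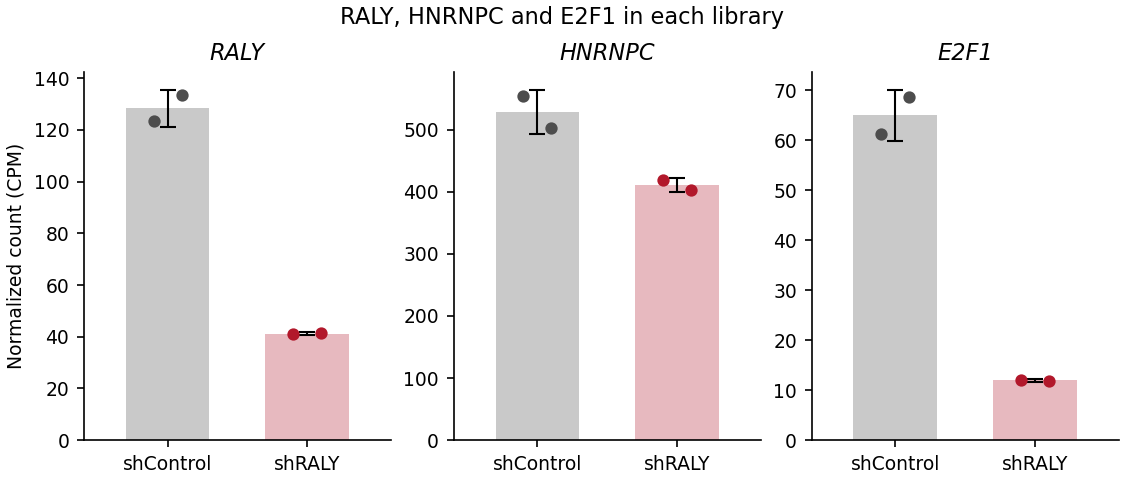
Normalised read counts (CPM, linear axis from 0) of RALY, HNRNPC and E2F1 in shControl and shRALY libraries; bars are means, error bars are SD and points are the 2 libraries of each group. RALY was at 41.2 CPM in shRALY against 128 CPM in shControl, and E2F1 at 12 against 64.9 CPM.

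Interferon genes and antiviral genes were among the largest rises in shRALY, and genes of DNA replication and cell division among the largest falls. RSAD2, an antiviral enzyme, had no counts in shControl and 39.5 ± 7.04 CPM in shRALY, at least 456-fold higher. IFNL1, an interferon lambda, went from 0 counts to 21.6 ± 0.40 CPM (at least 251-fold), GBP4 to 15.9 ± 3.92 CPM (at least 183-fold), IFI44L to 12.7 ± 1.07 CPM (at least 148-fold) and IFNL2 to 10.0 ± 1.48 CPM (at least 116-fold). IDO1, which degrades tryptophan, was at least 85.2-fold higher, the chemokine CXCL10 at least 73.8-fold, the interferon beta gene IFNB1 at least 68.4-fold and IFNL3 at least 66.4-fold, each from 0 control counts. MX2 had 1 control count and rose to 27.3 ± 0.43 CPM, a ratio of 956 with a 95% counting interval of 171 to 37800. OASL rose from 0.80 ± 0.11 to 431 ± 61.3 CPM and OAS2 from 0.26 ± 0.13 to 109 ± 5.15 CPM. The log2 fold change of OAS2 was 8.68, against 9.30 without shControl replicate 2. For MX2, shControl replicate 2 held the single control count, so no ratio can be formed without it, and the log2 fold change of MX2 was 8.69 without shControl replicate 1. The 12 genes with these largest rises each passed the edgeR test, with adjusted p between 1.27e-19 and 1.40e-09. IFNL2 and IFNL3 share 32.0% and 33.0% of their sequence words of 50 bases, so the division of reads between them is uncertain. Bounds are against a floor of 3 counts over the shControl group, and bounds and intervals cover counting error only.

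Among the falls, E2F8, a repressor of the E2F family, went from 16.2 ± 4.58 to 0.64 ± 0.22 CPM, 25.2-fold lower. MKI67, which encodes the proliferation marker Ki-67, fell 18.2-fold, from 510 ± 85.3 to 28.0 ± 4.11 CPM. FBXO43 was 18.1-fold lower, from 9.96 ± 1.31 to 0.52 ± 0.65 CPM. The log2 fold change of FBXO43 was -4.18, against -7.18 without shRALY replicate 1 and -3.33 without shRALY replicate 2. GTSE1 was 16.8-fold lower, E2F2 16.6-fold, FAM111B 16.4-fold, the histone chaperone gene ASF1B 15.4-fold and BIRC5, which encodes survivin, 13.9-fold. ERCC6L, TROAP, CENPF and the cohesin acetyltransferase gene ESCO2 were 13.2 to 13.5-fold lower. These 12 falls had edgeR adjusted p between 1.05e-16 and 2.76e-07. E2F1, on chromosome 20 at 33675683 to 33686404 and an activator of S-phase genes, fell from 64.9 ± 5.14 to 12 ± 0.23 CPM (log2 -2.44, SE 0.14; edgeR adjusted p = 1.07e-12).

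In all, 3274 genes were higher and 3245 lower in shRALY at an edgeR adjusted p under 0.05, 41.0% of the 15912 genes tested. Of these, 1112 were higher and 1045 lower by 2-fold or more. Protein-coding genes supplied 3019 of the rises and 2954 of the falls. TMM scaling centres the changes near 0, so the near-equal split depends on it. With library size alone, 2894 genes were higher and 3706 lower. All changes are relative to the other genes of a library, and a change in RNA per cell would not be seen. In 69.7% of tested genes the shRALY libraries both lay on the same side of both shControl libraries, against 33.3% by chance. The biological coefficient of variation was 9.3%. Without shRALY replicate 1 the counts were 2260 higher and 1897 lower, and without shRALY replicate 2 they were 2040 and 1980. With a filter of 10 CPM, 606 genes were higher and 607 lower by 2-fold or more.

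**Figure D2:**
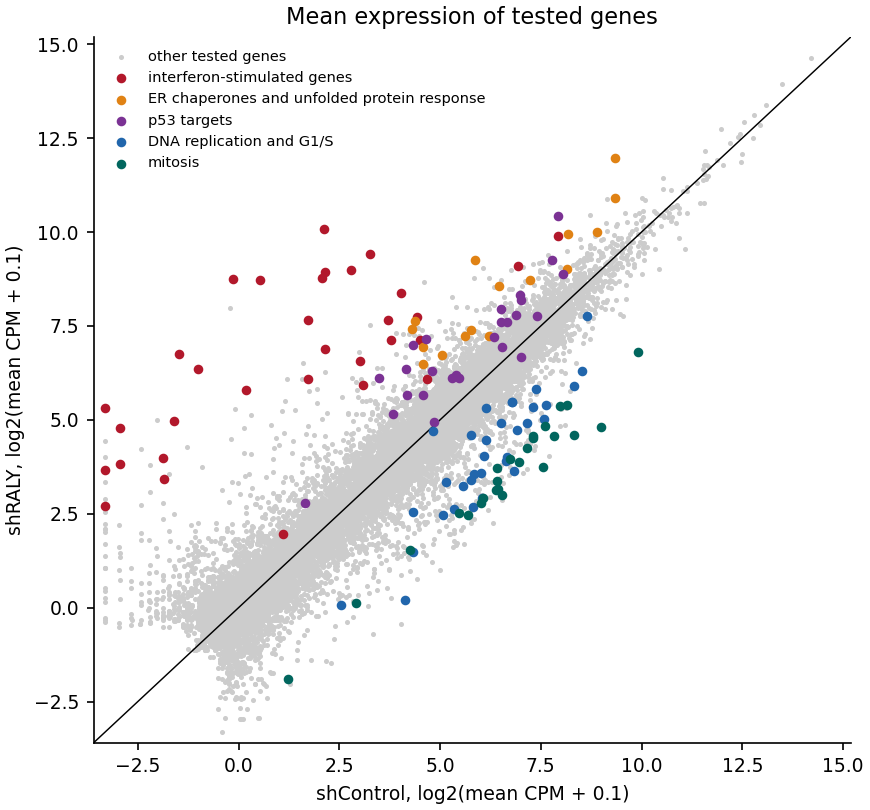
Mean expression of each tested gene in shControl (horizontal) and shRALY (vertical), both as log2(mean CPM + 0.1) over 2 libraries; the line marks equal expression and colours mark 5 gene lists. The 32 interferon-stimulated genes, all 16 genes of the ER chaperone list and 24 of 26 p53 targets passed the test above the line, and 32 of 33 DNA replication genes and all 25 mitosis genes passed it below the line.

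Interferon-stimulated genes rose together. All 32 listed genes were tested and all 32 were higher in shRALY (32 also when adjusted over the list alone), with a median log2 fold change of 6.08 (camera adjusted p = 4.51e-43; adjusted p = 0.125 with an estimated correlation). A listed gene with too few shControl counts for the filter was tested through shRALY alone, and could only be higher. IFIT2 rose 255-fold, from 4.26 ± 0.05 to 1089 ± 122 CPM. IFIT1 rose 72.3-fold, from 9.49 ± 0.86 to 686 ± 27.0 CPM, and IFIT3 rose 109-fold, from 4.07 ± 0.06 to 442 ± 41.8 CPM. The listed genes took 0.054% and 0.057% of counts in the shControl libraries and 0.714% and 0.775% in the shRALY libraries. Of 20 listed NF-kB targets and cytokines, 17 were tested, 15 were higher and none lower (15 and 0 adjusted over the list alone). The counts were also 15 higher and 0 lower at an unadjusted p under 0.05 and by DESeq2. The median log2 fold change was 2.01 (camera adjusted p = 2.38e-11, or 0.126 with an estimated correlation). The chemokine CXCL8 rose 15-fold, the adhesion molecule ICAM1 17.5-fold, the ubiquitin-editing enzyme TNFAIP3 7.72-fold and the apoptosis inhibitor BIRC3 4.36-fold. ICAM1 overlaps an opposite-strand gene over 23.6% of its exonic bases, and the counts cannot be assigned by strand. CCL2 and TNFAIP2 did not pass, at log2 0.23 and 0.21; TNFAIP2 passed without shControl replicate 2 (log2 0.39, edgeR adjusted p = 0.000283), with the replicate number as a block (edgeR adjusted p = 0.0259) and after a GC content and transcript length correction (edgeR adjusted p = 0.00101). The median of immune cell markers was 0.014 CPM in shControl and 0.126 CPM in shRALY beside these rises, over 14 markers, of which CD14 (7.32 ± 1.11 and 6.57 ± 2.02 CPM) and CORO1A (3.15 ± 0.35 and 3.17 ± 0.18 CPM) were abundant enough to test and neither passed.

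Genes of cell division and DNA replication fell across their lists. All 25 mitosis genes were lower (25 adjusted over the list alone), with a median log2 fold change of -3.11 (camera adjusted p = 2.37e-32; adjusted p = 0.125 with an estimated correlation). TOP2A, the topoisomerase that untangles sister chromatids, fell 8.68-fold, from 972 ± 66.6 to 112 ± 2.07 CPM, and CENPF fell from 320 ± 10.1 to 23.9 ± 0.23 CPM. Of 33 DNA replication and G1/S genes, 32 were lower and none higher (32 and 0 adjusted over the list alone). The counts were also 32 lower and 0 higher at an unadjusted p under 0.05 and by DESeq2. The median was -2.24 (camera adjusted p = 1.51e-30, or 0.125 with an estimated correlation). The replicative helicase subunits MCM4 and MCM5 fell 5.29-fold and 5.89-fold, MCM10 fell 8.73-fold, and RRM2, a subunit of ribonucleotide reductase, fell 9.22-fold, from 114 ± 18.3 to 12.3 ± 2.16 CPM. RRM2 shares 20.2% of its exonic bases with an overlapping gene on its strand, which leaves its counts uncertain. CCNE1 did not pass (28.0 ± 2.33 and 26 ± 3.24 CPM). Of 19 tested genes of homologous recombination and Fanconi repair, 18 were lower (18 adjusted over the list alone), with a median of -2.11 (camera adjusted p = 1.89e-14; adjusted p = 0.125 with an estimated correlation). BRCA1 fell 5.75-fold, from 105 ± 9.74 to 18.3 ± 0.90 CPM, FANCD2 6.65-fold, FANCI 5.64-fold and the nuclease EXO1 10.4-fold. RAD51D did not pass (26.7 ± 1.76 and 28.4 ± 2.22 CPM). Of 9 tested replication-dependent histone genes, whose main transcripts are not polyadenylated and so are poorly sampled here, 4 were higher and 1 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.149). HIST1H1C rose 2.62-fold and HIST1H2AC 2.24-fold, and HIST1H2BJ was lower at log2 -0.92, a call lost without shControl replicate 2 (edgeR adjusted p = 0.296), without shRALY replicates 1 and 2 (edgeR adjusted p = 0.136 and 0.0561) and with DESeq2 (adjusted p = 0.092).

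Targets of p53 rose. Of 26 listed targets, 24 were higher and 1 lower (24 and 1 adjusted over the list alone), with a median log2 fold change of 1.12 (camera adjusted p = 2.97e-16; adjusted p = 0.125 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 5.68-fold, from 241 ± 31.1 to 1370 ± 6.13 CPM. GADD45A rose 5.69-fold, SESN2 6.28-fold and BBC3, which encodes the pro-apoptotic PUMA, 6.21-fold. TP53I3 was lower (log2 -0.34, edgeR adjusted p = 0.0148), a call lost without shRALY replicate 1 (edgeR adjusted p = 0.112) or 2 (edgeR adjusted p = 0.361), and POLH did not pass (28.5 ± 0.69 and 30.5 ± 0.24 CPM). CCNE1, RAD51D, TP53I3, POLH and the other members named as exceptions to their list were chosen after their values were seen.

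Stress-responsive genes moved in different directions by list. All 16 ER chaperone and unfolded protein response genes were higher (16 adjusted over the list alone), with a median log2 fold change of 1.73 (camera adjusted p = 6.10e-20; adjusted p = 0.125 with an estimated correlation). HSPA5, the ER chaperone BiP, rose 6.17-fold, from 649 ± 49.8 to 4005 ± 38.7 CPM, HERPUD1 rose 10.4-fold, from 58.8 ± 1.15 to 614 ± 5.33 CPM, CRELD2 9.50-fold and the co-chaperone gene DNAJB9 8.57-fold. Of 20 ATF4 targets, 14 were higher and 3 lower (15 and 3 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 3.36e-07; adjusted p = 0.125 with an estimated correlation). DDIT3, which encodes CHOP, rose 31.6-fold, from 2.90 ± 0.79 to 91.7 ± 1.64 CPM, STC2 6.32-fold and TRIB3 4.65-fold; SESN2 stands in this list too. DDIT3 overlaps MARS on the opposite strand over 31.6% of its exonic bases. The lower members were PHGDH, of serine synthesis (log2 -0.56), and SLC7A11 and SLC3A2, the subunits of the cystine transporter (log2 -0.65 and -0.35). PHGDH lost its call without shRALY replicate 1 (edgeR adjusted p = 0.11), and SLC3A2 without shRALY replicates 1 and 2 (edgeR adjusted p = 0.153 and 0.184). ASNS, SHMT2 and ATF5 did not pass, at log2 0.77, 0.04 and 0.12; ASNS shares 82.0% of its sequence words with another gene and ATF5 overlaps an opposite-strand gene over 21.2% of its exonic bases, so both are uncertain. Of 20 tested immediate early genes, 18 were higher and 1 lower (18 and 1 adjusted over the list alone), with a median of 1.33 (camera adjusted p = 2.31e-12; adjusted p = 0.125 with an estimated correlation). The stress-induced transcription factor gene ATF3 rose 30.4-fold, from 2.21 ± 0.52 to 67.4 ± 9.43 CPM, EGR1 30.3-fold, KLF4 7.89-fold and JUN 5.11-fold. NR4A1 fell from 17.6 ± 2.57 to 9.53 ± 0.79 CPM, and FOSB did not pass at 0.80 ± 0.21 and 0.82 ± 0.23 CPM. Of 14 cytosolic heat shock genes, 12 were lower and none higher (12 and 0 adjusted over the list alone). The counts were also 12 lower and 0 higher at an unadjusted p under 0.05 and by DESeq2. The median was -0.73 (camera adjusted p = 3.64e-08, or 0.125 with an estimated correlation). HSP90AA1 fell 2.87-fold, from 2151 ± 229 to 750 ± 30.7 CPM, DNAJB1 2.78-fold and HSPA1A 3.07-fold. HSPA1A and HSPA1B share 72.6% and 73.5% of their sequence words, and their separate counts are uncertain. DNAJA1 and CRYAB did not pass, at log2 -0.17 and 0.04; DNAJA1 passed without shControl replicate 2 (log2 -0.25, edgeR adjusted p = 0.0137) and after a GC content and transcript length correction (edgeR adjusted p = 0.011). CRYAB overlaps an opposite-strand gene over 20.6% of its exonic bases and is uncertain.

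**Figure D3:**
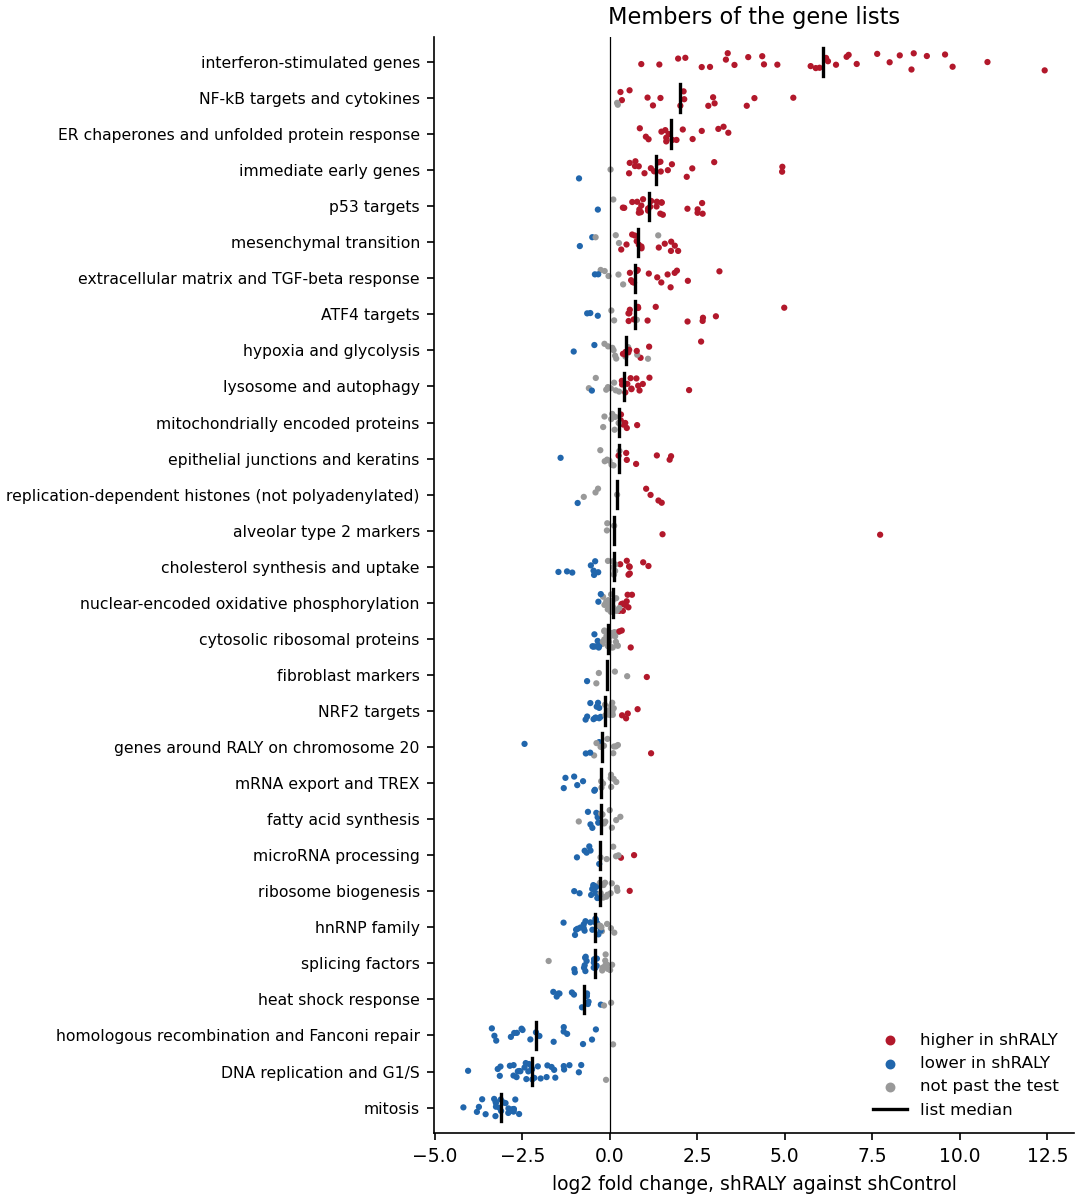
Fitted log2 fold changes (horizontal, shRALY against shControl) of the members of 30 gene lists, each point a gene coloured by whether it was higher, lower or not past the edgeR test; black bars are list medians, from -3.11 for mitosis to 6.08 for interferon-stimulated genes. Genes with no shControl counts are drawn at their fitted value, which is not a bound.

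Matrix and mesenchymal genes rose in part. Of 22 extracellular matrix and TGF-beta response genes, 15 were higher and 2 lower (17 and 2 adjusted over the list alone), with a median log2 fold change of 0.73 (camera adjusted p = 2.23e-08; adjusted p = 0.246 with an estimated correlation). PLAUR, the urokinase receptor, rose 8.76-fold, from 20.5 ± 0.81 to 179 ± 17.8 CPM, the basement membrane collagen gene COL4A1 rose 4.69-fold, COL5A1 3.77-fold and PLAU 3.61-fold; PLAU overlaps an opposite-strand gene over 31.1% of its exonic bases. LAMA3 and TGFB2 were lower at log2 -0.43 and -0.33. LAMA3 lost its call without shRALY replicate 1 (edgeR adjusted p = 0.231), and TGFB2 without shRALY replicate 1 or 2 (edgeR adjusted p = 0.276 and 0.218). TGFB2 also shares 26.4% of its sequence words with another gene. Of 20 mesenchymal transition genes, 14 were higher and 2 lower (16 and 2 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 4.15e-06; adjusted p = 0.159 with an estimated correlation). The integrin gene ITGA5 rose 3.62-fold, and SPARC and TGFBI rose 2.63-fold and 1.87-fold. TWIST1 and TWIST2, transcription factors that promote mesenchymal transition, were lower at log2 -0.86 and -0.50. TWIST1 lost its call without shControl replicate 2 (edgeR adjusted p = 0.145) and shRALY replicate 2 (edgeR adjusted p = 0.195) and with DESeq2 (adjusted p = 0.0845), and TWIST2 without shRALY replicates 1 and 2 (edgeR adjusted p = 0.199 and 0.0795). Of 15 tested epithelial junction and keratin genes, 7 were higher and 1 lower (7 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0495; adjusted p = 0.347 with an estimated correlation). The list lost its call without shControl replicate 1 (camera adjusted p = 0.0822) and with DESeq2 normalisation (camera adjusted p = 0.0504). The tight junction gene CLDN1 rose 3.36-fold and KRT19 3.27-fold, CLDN4 rose 2.53-fold and OCLN 1.68-fold, and TJP3 fell from 5.19 ± 0.47 to 1.94 ± 0.49 CPM.

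Markers of alveolar type 2 cells, fibroblasts and endothelial cells were mostly below the level needed for a test. Of 13 alveolar type 2 markers, 5 were tested and 2 were higher (2 adjusted over the list alone; median log2 0.12, camera adjusted p = 0.126). LAMP3 rose 211-fold, from 0.15 ± 0.13 to 31.8 ± 6.45 CPM; it encodes a lysosomal membrane protein that interferon also induces. The log2 fold change of LAMP3 was 7.72, against 7.03 without shControl replicate 1 and 8.99 without shControl replicate 2. HHIP rose 2.84-fold, and the surfactant genes listed had at most 4 counts in any library. The type 2 list passed without shRALY replicate 1 (camera adjusted p = 0.0421) or 2 (camera adjusted p = 0.0336). Of 12 fibroblast markers, 6 were tested, ACTA2 was higher (log2 1.06) and THY1 lower (log2 -0.65), as when adjusted over the list alone (camera adjusted p = 0.983). The fibroblast list had a median of -0.09, a mean of 0.06 and an upward camera direction. THY1 lost its call without shRALY replicate 2 (edgeR adjusted p = 0.0969), and an antisense gene overlaps 30.1% of the exonic bases of ACTA2. Of 10 endothelial markers, 1 was tested, ESAM, at 9.01 ± 0.45 and 11.6 ± 0.10 CPM (edgeR adjusted p = 0.128).

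Genes of RNA binding and splicing were lower by smaller amounts. Of 25 tested hnRNP family genes other than RALY, 18 were lower and none higher (21 and 0 adjusted over the list alone). At an unadjusted p under 0.05, 21 were lower and 0 higher, and by DESeq2 18 and 0. The median log2 fold change was -0.41 (camera adjusted p = 1.03e-07, or 0.178 with an estimated correlation). HNRNPUL1 fell 2.50-fold, from 615 ± 74.7 to 246 ± 16.5 CPM, the splicing repressor PTBP1 2.00-fold, HNRNPF 1.95-fold and HNRNPA0 1.90-fold. Of 26 splicing factors, 16 were lower and none higher (16 and 0 adjusted over the list alone). At an unadjusted p under 0.05, 18 were lower and 0 higher, and by DESeq2 16 and 0. The median was -0.43 (camera adjusted p = 3.15e-06, or 0.125 with an estimated correlation). SRSF3 fell 2.00-fold, from 319 ± 18.5 to 159 ± 1.81 CPM, and the SF3b subunit SF3B3 1.67-fold. SRSF1 fell 2.02-fold and U2AF2 1.63-fold; 56.6% of the exonic bases of SRSF1 lie under another gene on its strand. Of 15 tested mRNA export genes, 7 were lower and none higher (7 and 0 adjusted over the list alone). At an unadjusted p under 0.05, 9 were lower and 0 higher, and by DESeq2 7 and 0. The median was -0.25 (camera adjusted p = 0.00663, or 0.178 with an estimated correlation). The helicase gene DDX39A fell 2.03-fold, THOC7 2.41-fold and ALYREF 1.70-fold. THOC3, which shares 46.8% of its sequence words with another gene, was 2.49-fold lower. Of 13 microRNA processing genes, 6 were lower and 2 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.156), with AGO2, the slicing Argonaute, 1.92-fold lower and DROSHA 1.5-fold lower. The higher members were AGO4 (log2 0.69), which lost its call without shRALY replicate 2 (edgeR adjusted p = 0.0601), and DICER1 (log2 0.32), which lost it without shRALY replicate 1 (edgeR adjusted p = 0.106) or 2 (edgeR adjusted p = 0.408) and with library size alone (edgeR adjusted p = 0.0601).

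Ribosome biogenesis genes were lower in part. Of 27 such genes, 12 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median log2 fold change of -0.28 (camera adjusted p = 0.00233; adjusted p = 0.258 with an estimated correlation). The list lost its call without shRALY replicate 2 (camera adjusted p = 0.0918). FBL, the methyltransferase fibrillarin, fell 2.03-fold, from 272 ± 3.02 to 134 ± 0.94 CPM, UTP20 1.82-fold and NPM1 1.45-fold, and RRP12 was higher at log2 0.57; NPM1 shares 44.4% of its sequence words with other genes, a pseudogene first among them. Of 39 cytosolic ribosomal protein genes, 8 were lower and 3 higher (8 and 3 adjusted over the list alone; median -0.04, camera adjusted p = 0.434). RPS19 was the largest of the 3 rises, at 1.51-fold. RPS12 (log2 0.27) lost its call without shRALY replicates 1 and 2 (edgeR adjusted p = 0.29 and 0.267) and with library size alone (edgeR adjusted p = 0.0835), and shares 23.6% of its sequence words with another gene. RPS27 (log2 0.34) lost it without shControl replicate 1 (edgeR adjusted p = 0.0621), without shControl replicate 2 (edgeR adjusted p = 0.0649), without shRALY replicate 2 (edgeR adjusted p = 0.662) and with library size alone (edgeR adjusted p = 0.0611), and shares 23.1% of its sequence words with another gene. RPS4X fell 1.41-fold, a call lost without shRALY replicate 2 (edgeR adjusted p = 0.0863).

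FASN, the fatty acid synthase, was among several enzymes of lipid synthesis that fell. Of 15 fatty acid synthesis genes, 6 were lower and none higher (6 and 0 adjusted over the list alone; 1 higher at an unadjusted p under 0.05 and 0 by DESeq2), with a median log2 fold change of -0.25 (camera adjusted p = 0.048; adjusted p = 0.257 with an estimated correlation). The list lost its call without shRALY replicate 1, without shRALY replicate 2 and with DESeq2 normalisation (camera adjusted p = 0.0504). It also lost it with the replicate number as a block, a filter of 10 CPM and RLE size factors (camera adjusted p = 0.118, 0.0976 and 0.0501). FASN fell 1.54-fold, from 1075 ± 209 to 696 ± 53.4 CPM. Of 24 cholesterol synthesis and uptake genes, 8 were higher and 8 lower (8 and 8 adjusted over the list alone), with a median of 0.12, a mean of -0.01, an upward camera direction and a camera adjusted p of 0.797. STARD4, a sterol carrier, rose 2.15-fold, and EBP, a sterol isomerase, fell 2.11-fold. Of 24 NRF2 targets, 11 were lower and 4 higher (11 and 4 adjusted over the list alone; median -0.14, camera adjusted p = 0.167). SLC7A11 fell 1.57-fold, and AKR1C2 and AKR1C1, which share 52.2% and 28.7% of their sequence words, fell 1.62-fold and 1.47-fold. The higher members were ABCC3 (1.73-fold), ALDH3A1 (1.43-fold), ABCC2 (1.38-fold) and OSGIN1 (1.27-fold). ABCC2 lost its call without shRALY replicate 2 (edgeR adjusted p = 0.0548), and OSGIN1 without shControl replicate 1 (edgeR adjusted p = 0.0937), shRALY replicate 1 (edgeR adjusted p = 0.12) and shRALY replicate 2 (edgeR adjusted p = 0.267) and with library size alone (edgeR adjusted p = 0.0562). Of 22 hypoxia and glycolysis genes, 10 were higher and 2 lower (13 and 2 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 0.0104; adjusted p = 0.178 with an estimated correlation). The list lost its call without shRALY replicate 1 or 2 and with a filter of 10 CPM (camera adjusted p = 0.0735). It also lost it with the replicate number as a block (camera adjusted p = 0.114). HK2 rose 6.09-fold, from 1.03 ± 0.12 to 6.33 ± 1.26 CPM, VEGFA 1.84-fold and PFKP 1.70-fold, and PFKFB3, which drives glycolytic flux, fell 2.05-fold. GPI was lower at log2 -0.44, a call lost without shRALY replicate 1 (edgeR adjusted p = 0.0564) or 2 (edgeR adjusted p = 0.0693).

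Mitochondrial transcripts took 7.67% and 6.99% of counts in the shControl libraries and 8.88% and 8.66% in the shRALY libraries. Of 13 mitochondrially encoded protein genes, 6 were higher and none lower (6 and 0 adjusted over the list alone; 1 lower at an unadjusted p under 0.05 and 0 by DESeq2), with a median log2 fold change of 0.25 and a camera adjusted p of 0.063, which became 0.0362 with no filter on low counts. MT-ND3 rose 1.72-fold and MT-CO1 1.36-fold, from 18780 ± 796 to 25460 ± 115 CPM. MT-CO1 shares 49.5% of its sequence words with other genes, a pseudogene first among them, so its level is uncertain. Of 30 nuclear-encoded oxidative phosphorylation genes, 9 were higher and 2 lower (9 and 2 adjusted over the list alone; median 0.08, camera adjusted p = 0.15, or 0.0378 with no filter on low counts). COX4I1 rose 1.42-fold, from 206 ± 6.63 to 292 ± 7.06 CPM. UQCRFS1 and ATP5F1B were the lower members, at log2 -0.33 and -0.26. Without shRALY replicates 1 and 2, the edgeR adjusted p was 0.131 and 0.348 for UQCRFS1 and 0.278 and 0.405 for ATP5F1B, which was 0.0542 with no filter on low counts. Of 22 lysosome and autophagy genes, 13 were higher and 1 lower (14 and 2 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.000625; adjusted p = 0.145 with an estimated correlation). The phosphoinositide-binding autophagy gene WIPI1 rose 4.80-fold, the autophagy receptor SQSTM1 1.92-fold, the cathepsin gene CTSL 1.80-fold and HEXA 1.75-fold. WIPI1 and SQSTM1 overlap opposite-strand genes over 28.1% and 22.0% of their exonic bases. ATG16L1 was lower at log2 -0.52, a call lost without shRALY replicate 1 (edgeR adjusted p = 0.0987).

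Genes around RALY on chromosome 20 were examined as neighbours of the target. Of 14 tested neighbours, 4 were lower and 1 higher (4 and 1 adjusted over the list alone; median log2 -0.22, camera adjusted p = 0.232). E2F1 was the lowest, NCOA6, a nuclear receptor coactivator gene, fell 1.61-fold and MAP1LC3A rose 2.26-fold. AHCY (log2 -0.31) lost its call without shRALY replicate 1 (edgeR adjusted p = 0.227) or 2 (edgeR adjusted p = 0.291). PXMP4 (log2 -0.56) lost it without shControl replicate 2 (edgeR adjusted p = 0.0647), shRALY replicate 1 (edgeR adjusted p = 0.233) or shRALY replicate 2 (edgeR adjusted p = 0.0612) and with DESeq2 (adjusted p = 0.0567). Over the 30 lists with at least 5 tested members, 20 passed camera at its preset correlation of 0.01. At an estimated correlation 0 passed, and 11 had an unadjusted camera p under 0.05. By fry, which tests whether a list's own genes move on balance in 1 direction, 26 passed. Some of them had not passed camera. These were genes around RALY (fry adjusted p = 0.00182), alveolar type 2 markers (0.0107) and NRF2 targets (0.0134). Replication-dependent histones (fry adjusted p = 0.0158), microRNA processing (0.0291) and mitochondrially encoded proteins (0.039) were the others.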

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

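Of the settings described here, the GC content and transcript length correction and the test against a 1.2-fold change were chosen only after the results were seen. No called direction reversed among the RALY value, the 208 named genes and the 30 lists under any alternative run, and 168 of the named genes kept their side of the threshold in each alternative that tested them. The log2 fold change of RALY lay between -1.70 and -1.57 without 1 library. The count of genes higher was 2837 with DESeq2, 3321 with RLE size factors, 2894 with library size alone, 3226 with no filter on low counts, 2712 with a filter of 10 CPM, 3973 after the GC content and transcript length correction and 2317 against a 1.2-fold change, where 3274 were reported. The matching counts of genes lower were 2628, 3146, 3706, 3138, 2637, 3928 and 2183, where 3245 were reported. Library size alone moved the median of all genes by -0.056. Leaving out 1 library gave between 2040 and 3559 genes higher and between 1897 and 3499 lower, with the lone library left in a group assumed to vary like the other group. With a filter of 10 CPM, 606 genes were higher and 607 lower by 2-fold or more, from the 10017 genes tested instead of 15912. Calls shared with these alternatives never had the opposite sign (0 in each). Without a shRALY library, the spread came from the shControl pair alone. Its chi-square per gene was 11.8, against 4.92 for the shRALY pair. A call lost there can reflect that wider spread as well as a changed effect. The log2 fold change of HNRNPC was -0.385 and -0.324 without shRALY replicates 1 and 2, against -0.363 with all libraries. That of RPS27 was 0.138 without shRALY replicate 2, against 0.339.

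With an estimated correlation between genes, each of the 20 lists that camera called was no longer past the threshold. The adjusted p was 0.125 for DNA replication and G1/S, mitosis, homologous recombination, p53 targets, interferon-stimulated genes, immediate early genes, ATF4 targets, ER chaperones, heat shock and splicing factors, and 0.126 for NF-kB targets. It was 0.145 for lysosome and autophagy, 0.159 for mesenchymal transition, 0.178 for hypoxia, the hnRNP family and mRNA export, 0.246 for extracellular matrix, 0.257 for fatty acid synthesis, 0.258 for ribosome biogenesis and 0.347 for epithelial junctions. For p53 targets, splicing factors, hypoxia, lysosome and autophagy, mRNA export and fatty acid synthesis, the estimated correlation lay below the preset 0.01. It was -0.012, -0.008, -0.042, -0.031, -0.058 and 0.005 in that order. A correlation above the preset is thus argued against as the cause of the loss for these lists. With an estimated correlation, camera also uses only the 2 residual degrees of freedom of the libraries, which limits how small its p can be. None of the 30 lists went below an adjusted p of 0.125 in that test. Failing it therefore does not show that the genes of a list did not move. No other cause was tested for the changes in list calls. Fatty acid synthesis had a camera adjusted p of 0.0504 with DESeq2 normalisation, 0.0501 with RLE, 0.0976 with the 10 CPM filter and 0.0278 to 0.252 without 1 library. Epithelial junctions had 0.0504 with DESeq2 normalisation, 0.0501 with RLE, 0.0606 with library size alone, 0.053 with the 10 CPM filter, 0.0511 after the GC content and transcript length correction and 0.01 to 0.0822 without 1 library. Hypoxia and glycolysis had 0.0735 with the 10 CPM filter and 0.0124 to 0.0665 without 1 library, ribosome biogenesis 0.000662 to 0.0918 and alveolar type 2 markers 0.0336 to 0.169. Mitochondrially encoded proteins passed at 0.0362 with no filter on low counts and 0.0398 after the GC content and transcript length correction, and nuclear-encoded oxidative phosphorylation at 0.0378 with no filter.

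With the replicate number as a block, 3639 genes were higher and 3619 lower, and 6508 of the 6519 reported calls were shared. In that block fit, fatty acid synthesis had a camera adjusted p of 0.118, hypoxia and glycolysis 0.114 and alveolar type 2 markers 0.0388; the cause was not tested. Deviations of libraries with the same number correlated at 0.072 across genes, and the labels give the number no meaning. Depth limited the lowest levels: 3 counts correspond to 0.161 to 0.179 CPM, and 28979 genes had no count in any library.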

Other observations

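The antigen presentation, sensor, interferon, collagen, tubulin, lamin and ZNF groups, the choice of RPS26 and the tests of technical explanations in this part were chosen only after the results were seen, while the gene lists used in those tests were set earlier; for the GC content and transcript length correction, the bound was set before its value was computed.

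Genes of antigen presentation and of nucleic acid sensing were higher in shRALY. All 17 tested genes of class I antigen presentation were higher, with a median log2 fold change of 1.87. HLA-B, a class I heavy chain, rose from 2.11 ± 0.49 to 44.9 ± 3.75 CPM, B2M, the shared light chain, from 159 ± 31.9 to 571 ± 9.90 CPM, and the peptide transporter gene TAP1 from 42.2 ± 5.38 to 257 ± 16.5 CPM (n = 2 per group). Of 14 tested sensors of foreign RNA and DNA and their adaptors, 12 were higher, MAVS was lower (log2 -0.33) and TMEM173 did not pass. MAVS lost its call without shControl replicate 2 (edgeR adjusted p = 0.062), shRALY replicate 1 (edgeR adjusted p = 0.443) and shRALY replicate 2 (edgeR adjusted p = 0.0914). IFIH1, which encodes the RNA sensor MDA5, rose from 3.18 ± 0.01 to 203 ± 25.9 CPM, and DDX58, which encodes RIG-I, from 16.3 ± 1.04 to 333 ± 20.7 CPM. Among 22 annotated interferon genes, 7 had enough counts to test and all 7 were higher. IFNB1, IFNL1, IFNL2, IFNL3 and IFNL4 had 0 control counts and passed the filter through shRALY alone. A fall was therefore not possible for them. IFNA1 shares 60.7% of its sequence words with another gene. It lost its call without shControl replicate 2 (log2 1.61) and without shRALY replicate 2 (log2 2.105). The log2 fold change of IFNA1 was 2.26, against 3.62 without shControl replicate 1 and 1.61 without shControl replicate 2. IFNE rose from 2.48 ± 0.60 to 7.16 ± 0.10 CPM.

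Of 24 tested collagen genes, 16 were higher and 8 did not pass. Of these 8, COL18A1 passed without shControl replicate 2 (log2 0.33, edgeR adjusted p = 0.0017) and after the GC content and transcript length correction (edgeR adjusted p = 0.0255). COL7A1, the collagen of anchoring fibrils, rose from 174 ± 26.1 to 580 ± 42.6 CPM. Of 14 tested tubulin genes, 8 were lower and 1 higher; TUBB fell from 1385 ± 38.1 to 521 ± 1.55 CPM, and the higher gene, TUBB2A (log2 0.55), shares 65.5% of its sequence words with another gene and lost its call without shRALY replicate 2 (edgeR adjusted p = 0.262). The lamin genes LMNB1 and LMNB2 fell, from 143 ± 0.71 to 27.3 ± 2.25 CPM and from 260 ± 54.0 to 62.1 ± 3.39 CPM. LMNA rose from 646 to 818 CPM (log2 0.34), a call lost without shRALY replicate 1 (edgeR adjusted p = 0.106) or 2 (edgeR adjusted p = 0.194). Of 376 tested genes with a ZNF symbol, 67 were lower and 27 higher. Over all 15912 tested genes, 3245 were lower and 3274 higher. The share of ZNF genes lower was slightly below that share, and the share higher was well below it. Their median log2 fold change was -0.118, against -0.012 over all tested genes. ZNF367 fell from 30.2 ± 0.63 to 4.98 ± 0.04 CPM, and ZNF467 rose from 9.84 ± 1.36 to 35.3 ± 2.05 CPM.

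Interferon-stimulated genes were higher in shRALY, all 32 of those listed. Immune cells among the shRALY cells are argued against by single markers. CD3D, CD3E, MS4A1, LYZ, FCGR3A and TYROBP had 0 counts in every library. PTPRC had 5 counts in shRALY replicate 1 and 0 in shRALY replicate 2. CD14 was the highest marker, at 6.57 CPM in shRALY and 7.32 CPM in shControl. The median of the 14 immune cell markers was 0.126 CPM in shRALY, but a median over several lineages could miss a single lineage. An effect of the hairpin or the virus preparation other than loss of RALY stays open, since the labels hold 0 hairpin sequences and no further arm. The sample titles name no second hairpin against RALY. The shControl cells also received a hairpin lentivirus, but dose and preparation are not given. Loss of RALY itself remains a biological explanation that this design cannot separate from the hairpin.

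RPS26, a ribosomal protein gene, fell 12.9-fold, from 210 ± 5.35 to 16.3 ± 0.21 CPM (log2 -3.69, SE 0.12; edgeR adjusted p = 2.69e-16). Reads counted to RPS26 pseudogenes instead are argued against, since 30 annotated pseudogenes gained -0.356% of the 193 CPM lost, and 27 genes sharing sequence words with it (25% of its words in all) gained -8.35%. A general fall of ribosomal protein transcripts is argued against too: the 39 listed genes had a median of -0.043 (SD 0.239), and the 82 ribosomal protein genes other than RPS26 a median of -0.063 (SD 0.332), with RPS13 the lowest at log2 -1.32. The RALY hairpin acting on RPS26 directly stays open, as the labels give 0 hairpin sequences. A change through RALY loss also stays open.

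Of 58 genes of DNA replication and mitosis, 57 were lower in shRALY, and the 58 had a median log2 fold change of -2.75 (SD 0.813). A correction for GC content and transcript length left the median at -2.748 (SD 0.804), with 57 genes past the test before and after, while the trend it removed ran from -0.253 to 0.095. Dilution by the 32 listed interferon-stimulated genes is argued against, as these took at most 0.775% of the counts of a shRALY library. Other induced transcripts were not counted in that share. RALY loss, the interferon response and other effects of the hairpin stay open, and no test here tells them apart.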
